A study of Arabidopsis thaliana with 60 samples.

How the data were processed

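Chromatin was profiled by ChIP-seq (sequencing of DNA pulled down with an antibody against a histone mark) in 8-day-old Arabidopsis thaliana seedlings. The 60 libraries were 36 ChIP and 24 input libraries. In the single-end series, H3K27me3, the repressive mark set by Polycomb repressive complex PRC2, and trimethylation of histone H3 lysine K4, found at transcribed genes, were profiled with 2 libraries per genotype and mark. The genotypes were the Landsberg erecta wild type (Ler), ult1-2, ult1-3 and 35S::ULT1, and the Columbia wild type (Col-0) with ref6-3. In the paired-end series, H3K27me3 was profiled in Col-0, in each of the single mutants swn-7, clf-28 and ult1-3, and in the double mutants that join ult1-3 to either of the others, with 2 libraries per genotype. The antibody tag of the labels writes histone H4 for the K4 libraries and the titles write K4 alone, so the mark is called K4 trimethylation here. Per the labels' protocols, technical ChIP reactions on one nuclear extract were pooled for each sample. Nothing in the labels says that the libraries of one genotype came from separate batches of plants. The p-values of limma and the permutation tests thus measure only the spread between these libraries, which may be technical. Fisher's exact tests treat genes as independent and measure no spread between libraries. Neighbouring genes can share a peak, which makes the p of these tests too small.

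Per the submitters' processing notes, the build was TAIR10 and the tools included CASAVA 1.8.2, BWA 0.6.2-r126, SAMtools 0.1.19, Picard 1.93, bedtools 2.17.0-97 and SICER 1.1 for the single-end series. For the paired-end series the notes named BWA 0.7.17-r1188, SAMtools 1.16.1, Picard 2.26.10, bedtools 2.30.0 and SICER 1.1. The role of each tool and its parameters are not given in the sources used here. The authors deposited 24 single-end peak lists, 1 for each library, and 6 paired-end lists, 1 for each genotype, and how the 2 libraries were combined in each of those 6 is not given in the sources used here. The files have no header. In the single-end lists the deposited values per peak were read as the raw read count of the ChIP library, the read count of the control library and an adjusted p-value (q-value), from the column order of a SICER summary and from the values. The deposited q-values were all below 0.0001, the largest being 9.99e-05. The paired-end lists carry 1 whole number per peak, treated as the authors' own score of unstated unit and used only to rank peaks within a list and to describe it. Peaks lay on windows of 200 bp and no 2 peaks of a list were closer than 600 bp. Depth before peak calling was not used here; the reads inside peaks ranged from 8.79 M (M, 1e6; H3K27me3, Col-0 library 2) to 22.5 M (K4, ref6-3 library 2). The depth of the paired-end lists is unknown.

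Lists were matched to samples by name. In 2 K4 lists, Ler and ult1-2, the library number in the name differs from that in the labels, so these were assigned to their genotype only. For K4, library numbers in this text, in the split by number and in the replicate block are those of the list names. The 2 columns of control counts of these lists could not be given to a sample and were not used here. Gene names and positions came from a RefSeq gene table of assembly TAIR10.1 with 27444 protein-coding genes of the nuclear chromosomes (37899 genes of all kinds). The gene table and the peaks were checked for a shift by finding, in each of 112 windows along the chromosomes, the shift that best aligned K4 peaks with genes. The best shift was 0 in 97 windows and at most 100 bp in all. All 183 members of the 9 gene lists were found in the table. The table holds no strand and a genome sequence was not used here. For this reason, the K4 rule used cover anywhere in the gene instead of its first 500 bp, limma used the percent of the whole gene for K4, and a search for the DNA motif bound by REF6 was not run.

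A gene was marked by H3K27me3 in a library when peaks covered at least 50% of its body. It was marked by K4 trimethylation when peaks covered at least 500 bp or at least 50% of its body, whichever was less. A gene was lost when it was marked in both wild-type libraries and in neither mutant library, and gained in the reverse case. This is a rule and gives no p-value. To show what the rule gives between libraries of one kind, it was also applied to the other 2 ways of splitting the same 4 libraries, by library number and crossed. Values for genes are the percent of the gene body covered, as mean ± SD over 2 libraries. Library totals and peak-set similarity (the Jaccard index, shared bp over the union) were compared between genotypes with exact permutation tests over all 105 ways to part the 8 Ler-family libraries into 4 genotypes. The 4 Col-0 and ref6-3 libraries give 3 partitions and no p below 0.333. The covered percent was also tested gene by gene with limma (trend and robust shrinkage, Benjamini-Hochberg adjustment, threshold 0.05) over the 8 Ler-family libraries and, separately, over the 4 Col-0 and ref6-3 libraries. Covers move in steps, and 5453 of the 10798 H3K27me3 genes of the Ler family had no residual variance at all, which left limma's prior with 0.0654 degrees of freedom. Genes with tiny, exactly repeated differences then passed, so adjusted p-values of single genes are given with an added variance floor of one 200-bp window, chosen after the data were seen. The 6 paired-end lists were compared as values only, with no test and no SD, and gene lists were placed among 10000 random lists of the same size matched on cover in Col-0. Overlaps of calls used Fisher's exact test, two-sided, and overlaps that share the Ler libraries are given beside 100 simulations of unchanged genotypes. Gene lists were tested with Fisher's exact test over 144 combinations of list, mark, genotype and direction.

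The sample groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The lists were floral identity, flowering time, meristem and boundary, seed and embryo, Polycomb and Trithorax, housekeeping, auxin, root and leaf polarity genes. The rule named the targeted gene, the 10 lost and 10 gained genes with the largest change in covered length (by limma p-value for K4), and each list member that was called or passed limma. Examples in the text were taken from that set, and genes named outside it are said to be so. Steps were tested on simulated data drawn from the Ler libraries alone, with 200 changed genes in a simulated ult1-2. The changed genes were set to no cover or to full cover in both simulated libraries. Recovery of partial changes was therefore not tested. The rule recovered 198 of 200 for each mark over 27444 genes and called 47 unchanged genes for H3K27me3 and 114 for K4. Over 8998 genes limma recovered 197 for H3K27me3, and 159 with the floor, with 14 and 0 unchanged genes called; over 18402 genes it recovered 162 for K4, and 133 with the floor, with 15 and 6. The alternatives tried were other cover minimums (1 bp, 20%, 80%), a stricter peak threshold (q below 1e-10, or the upper 75% of paired-end scores), equal numbers of peaks, merging of close peaks, all annotated genes, other limma settings, a replicate block and leaving out each library. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.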

Results

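The data were peak lists of 2 histone marks in Arabidopsis seedlings with altered ULTRAPETALA1 (ULT1), a SAND-domain protein of the trithorax group, altered REF6, a demethylase that removes H3K27me3, or mutated CLF or SWN, the methyltransferase subunits of PRC2 that set it. The Ler family held the Ler wild type, 2 mutant alleles (ult1-2 and ult1-3) and 35S::ULT1, which expresses ULT1 from a strong viral promoter. Col-0 and ref6-3 formed a second pair, and 6 genotypes in Col-0 background formed the paired-end series. Single-end H3K27me3 lists held 6379 to 9945 peaks with 8.79 to 22.4 M ChIP reads (M, 1e6) inside them, and K4 lists held 15527 to 16510 peaks with 16.5 to 22.5 M reads. The paired-end lists held 3703 to 5987 peaks.

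ULT1 (AT4G28190) was the targeted gene of the Ler family. Peaks of H3K27me3 covered 49.7% ± 0 of ULT1 in Ler (SD, n = 2; peak on chromosome 4, 13985601 to 13987000). Cover was 0% ± 0 in ult1-2, 46.2% ± 5.02 in ult1-3 and 85.2% ± 0 in 35S::ULT1. Peaks of K4 trimethylation covered 60.4% ± 5.02 of ULT1 in Ler, 67.5% ± 5.02 in ult1-2, 81.7% ± 5.02 in ult1-3 and 71.0% ± 10.0 in 35S::ULT1. In the paired-end lists, H3K27me3 covered 74.9% of ULT1 in Col-0, 0% in ult1-3, 71.0% in clf-28, 56.8% in swn-7, 71.0% in ult1-3 clf-28 and 35.5% in ult1-3 swn-7. REF6 (AT3G48430) carried no H3K27me3 peak in Col-0 or ref6-3, and K4 peaks covered 22.5% ± 2.55 of it in Col-0 and 45.8% ± 0 in ref6-3. CLF and SWN carried no H3K27me3 peak in any paired-end list. A mark over a mutated gene does not measure its product, so these values do not check the labels.

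**Figure D1:**
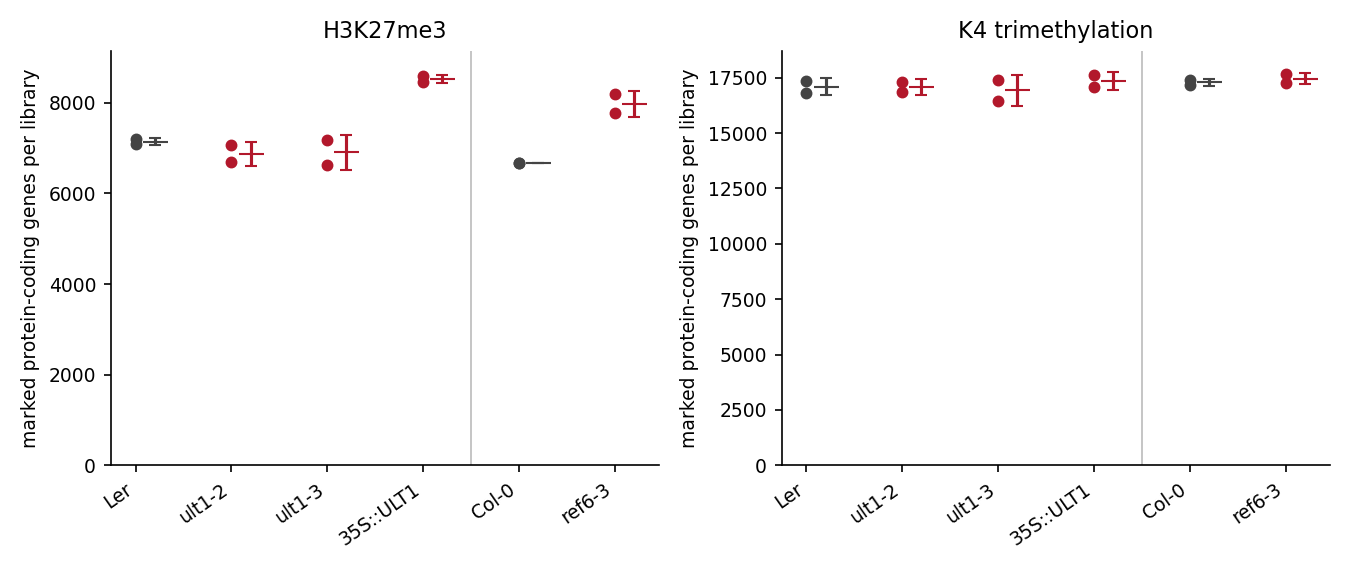
Protein-coding genes marked by H3K27me3 (left) or K4 trimethylation (right) in each single-end library, with the vertical axis in genes, points for libraries and bars for mean ± SD (n = 2). The 35S::ULT1 libraries marked 8465 and 8584 genes by H3K27me3 and the Ler libraries 7192 and 7083.

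The first comparison asked how loss of ULT1 changed H3K27me3. AT1G27570, under a peak on chromosome 1 (9574201 to 9584600), was covered for 100% ± 0 in Ler and 0% ± 0 in both mutants (n = 2 each). In ult1-2, lost genes included AIL5, an AP2-domain transcription factor, from 100% ± 0 to 46.0% ± 0.228, and the NAC-domain factor gene NAC047, from 77.5% ± 7.31 to 0% ± 0. MAF5, a relative of the flowering repressor FLC, went from 64.4% ± 0 to 35.1% ± 2.76. In ult1-3, GONST5, of the nucleotide-sugar transporter family, went from 100% ± 0 to 0% ± 0, and AT4G32230, which lies within 3 Mb of ULT1, was gained, from 0% ± 0 to 100% ± 0. The mutants marked 6875.5 ± 261 (ult1-2) and 6910.0 ± 390 genes (ult1-3), against 7137.5 ± 77.1 in Ler.

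By the rule, ult1-2 lost 184 genes and gained 85, and ult1-3 lost 146 and gained 73. Many of these genes differed in the same way between Col-0 and Ler: 56.5% of losses and 51.8% of gains in ult1-2, and 63.7% and 71.2% in ult1-3. Calls of simulated unchanged genotypes did so in 37.1% and 14.5% of cases, from the shared Ler libraries alone, and in 35S::ULT1 33.9% and 7.08% did. The other 2 splits of the same libraries gave 49 and 47 calls for ult1-2, against 269, and 45 and 71 for ult1-3, against 219. With limma and the variance floor no gene passed in either mutant (285 genes in ult1-2 and 242 in ult1-3 at an unadjusted p under 0.05); without the floor 320 and 355 genes passed, and 448 to 565 and 486 to 700 when any 1 library was left out. The smallest adjusted p with the floor among the genes named here was 0.149 for AT1G27570 in ult1-2. With the floor, limma's unadjusted p fell under 0.05 in a smaller share of the 10798 tested genes than 0.05. The floored test was thus strict here, and the lack of passing genes does not show that no gene changed. The 2 mutants shared 76 lost and 24 gained genes. Independent lists would share 3.86 and 0.308, and unchanged genotypes simulated against the same Ler libraries shared a mean of 0.360 and 0.540, though with a mean of only 11.9 lost and 18.2 gained genes each, far shorter lists. Part of the excess may come from the shared Ler libraries. Leaving out 1 library loosens the rule, so its counts could only stay or rise, here and in the other comparisons. Without library 3 of ult1-2 the lost count was 456, and without library 3 of ult1-3 it was 484. Without library 1 of these mutants the gained counts were 169 and 205, and without Ler library 3 the lost counts were 302 and 252. Without Ler library 1 the gained counts were 139 and 120. In ult1-3 a minimum of 1 covered bp raised the lost count to 225, and all annotated genes raised the gained counts to 149 and 123.

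In 35S::ULT1, more genes gained H3K27me3 than lost it, some of them partly covered in Ler already, such as PIN4, an auxin efflux carrier gene (26.8% ± 0 in Ler). RLP23, an immune receptor-like protein, rose from 0% ± 0 to 100% ± 0 (n = 2 each; chromosome 2, 13858001 to 13866000; limma adjusted p = 0.0191 with the floor). SPL3, an SBP-box promoter of flowering, rose from 0% ± 0 to 93.3% ± 0 (adjusted p = 0.0249), and CA1, a chloroplast carbonic anhydrase, from 0% ± 0 to 70.8% ± 6.67 (adjusted p = 0.0191). The potassium channel gene KT2/3 rose from 0% ± 0 to 73.7% ± 10.1 (adjusted p = 0.0191). In the other direction, the histone H2A gene HTA4 fell from 100% ± 0 to 0% ± 0 (adjusted p = 0.0191). AGO10, an Argonaute active in the shoot meristem, went from 52.0% ± 2.29 to 19.5% ± 0 and did not pass with the floor (adjusted p = 0.147).

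The rule gave 1173 gained and 62 lost genes, and the other 2 splits of these libraries gave 14 and 8 calls. With limma and the floor 711 genes passed, 693 of them higher, against 2453 without the floor. The 35S::ULT1 libraries held 9578 and 9945 peaks, of which 1931 (20.2%) and 2219 (22.3%) touched no Ler peak; these new peaks had a median width of 800 bp against 2400 bp for the others. In ult1-2 and ult1-3 the share of such peaks was 1.68% to 4.21%. Genotypes of the Ler family differed in the number of H3K27me3 peaks (exact permutation test, two-sided, p = 0.0476), not detectably in covered length (p = 0.124) or marked genes (p = 0.0762). With the library number as a block, the difference in peak number did not pass (exact permutation test, p = 0.0833). Peak sets of one genotype had a mean Jaccard index of 0.911 and those of different genotypes 0.814 (exact permutation test, one-sided, p = 0.00952, the smallest the design allows). Pairs of 35S::ULT1 with another genotype had 0.706 to 0.795, and pairs of different genotypes without it 0.867 to 0.900. The 2 ult1-3 libraries had 0.891. The test therefore does not show that ult1-2 and ult1-3 differ from Ler or from each other. With the peaks limited to 6920 in every library, 655 genes were gained and 137 lost, and limma called 1448. Without Ler library 3 the lost count was 101, without 35S::ULT1 library 1 it was 94, and with all annotated genes 139. Without the floor, limma called 855 genes when 35S::ULT1 library 1 was left out and 881 without library 3, against 2453.

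Loss of REF6 gave gains over many genes. The transporter genes ABCB14 (chromosome 1, peak 9763001 to 9774200) and AGL18, a MADS-box repressor of flowering, rose from 0% ± 0 in Col-0 to 100% ± 0 in ref6-3 (n = 2 each; limma adjusted p = 1.49e-05 for both with the floor). The auxin genes YUC3, a flavin monooxygenase of auxin synthesis, and PIN7, an auxin efflux carrier, rose from 0% ± 0 to 81.6% ± 12.5 (adjusted p = 0.000140) and from 14.4% ± 4.08 to 79.4% ± 4.08 (adjusted p = 0.00606). DAA1, an ATPase gene, rose from 0% ± 0 to 82.4% ± 2.77 (adjusted p = 0.000127), while the paired-end Col-0 list covered it for 88.3%. AT1G58400 fell from 98.8% ± 1.68 to 0% ± 0 (adjusted p = 1.62e-05).

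In ref6-3, 1378 genes were gained and 213 lost, against 38 and 46 calls in the other 2 splits. With limma and the floor, 1731 genes passed, 1527 higher and 204 lower. The ref6-3 libraries marked 7982 ± 286 genes and the Col-0 libraries 6669 ± 1.41 (n = 2 each; exact permutation test, p = 0.333, the smallest that 3 partitions allow). Without Col-0 library 2 the lost count was 379, and without ref6-3 library 2 it was 365. Without ref6-3 libraries 1 or 2 limma without the floor called 840 or 1126 genes, against 1876. The genes gained in ref6-3 and in 35S::ULT1, each against its own wild type, overlapped: of 19570 genes under 50% cover in all 4 wild-type libraries, 1184 and 1018 were gained and 262 in both, against 61.6 for independent lists (Fisher's exact test, two-sided, p = 1.83e-98, adjusted p = 2.01e-97 over 11 overlaps).

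K4 trimethylation changed at few genes. The neighbours AT1G45165 and AT1G45163, under a K4 peak on chromosome 1 (17089601 to 17091400), went from 100% ± 0 and 91.9% ± 0 in Ler to 0% ± 0 in all 3 other genotypes (n = 2 each; limma adjusted p = 1 in each with the floor), so that Ler stood apart at these genes. In 35S::ULT1, BRC1, a TCP factor that restrains branching, rose from 0% ± 0 to 55.4% ± 11.2 (limma adjusted p = 0.00768 with the floor), and SEP3, a MADS-box factor of floral organ identity, went from 0% ± 0 to 50.2% ± 16.4 (adjusted p = 0.401). In ult1-3, PAN, a bZIP factor of flower development, went from 0% ± 0 to 26.0% ± 0 (adjusted p = 1), and AT4G32230 near ULT1, which gained H3K27me3, went from 57.9% ± 0 to 0% ± 0 (adjusted p = 0.304). In ref6-3, the sieve-element gene SEOR1 fell from 27.4% ± 0 to 0% ± 0 (adjusted p = 4.24e-05) and AIL5 rose from 0% ± 0 to 26.9% ± 0 (adjusted p = 5.55e-05).

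K4 losses and gains numbered 38 and 35 in ult1-2, 76 and 59 in ult1-3, 20 and 72 in 35S::ULT1 and 63 and 115 in ref6-3. Unchanged genotypes simulated against the same Ler libraries had a mean of 62.5 lost and 9.52 gained genes. The losses in ult1-2 and 35S::ULT1 were below that mean and those in ult1-3 little above it. Of the losses and gains, 60.5% and 57.1% in ult1-2, 64.5% and 64.4% in ult1-3 and 50.0% and 23.6% in 35S::ULT1 also differed in this way between Col-0 and Ler, against 3.94% and 21.3% of the calls of simulated unchanged genotypes. Splitting the same libraries by the number in the list names, which for 1 list each of Ler and ult1-2 is not the labels' number, gave 510, 483, 485 and 159 calls, more than the genotypes in the Ler family. K4 peak sets of one genotype had a mean Jaccard index of 0.835 and those of different genotypes 0.861 (exact permutation test, one-sided, p = 0.781). With the number in the list names as a block, sets of one genotype were more alike by 0.00692 (exact permutation test, p = 0.0417). The result thus rests on the block, and the labels do not say that a number marks a batch. With limma and the floor 0 genes passed in ult1-2 (51 at an unadjusted p under 0.05), 2 in ult1-3, 3 in 35S::ULT1 and 147 in ref6-3; without it 106, 159, 111 and 1349 passed. The 51 genes of ult1-2 were a smaller share of the 18523 tested than 0.05, so the floored test was strict for K4 too. Few passing genes therefore do not show that few changed. Leaving out 1 library could again only keep or raise the counts of the rule. Without Ler library 3 the gained counts were 220 (ult1-2), 209 (ult1-3) and 337 (35S::ULT1). Without Ler library 1 the lost counts were 181, 227 and 95. Without library 3 of ult1-2, ult1-3 or 35S::ULT1 the lost counts were 249, 431 and 192, and without library 1 the gained counts were 173, 232 and 302. For ref6-3, 303 genes were gained without its library 1 and 256 without Col-0 library 2, and 165 were lost without Col-0 library 1 and 155 without ref6-3 library 2. Under a stricter peak threshold the lost counts were 18, 47 and 13 in the 3 Ler-family genotypes. With the 80% setting of the cover minimum, 336 genes were gained in ref6-3.

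The marks were then compared at the same genes. Of the 629 genes that gained H3K27me3 in ref6-3 and carried K4 trimethylation in Col-0, 31 (4.93%) lost the K4 mark. Of the other K4-marked genes that H3K27me3 left unmarked in both Col-0 libraries, 0.0926% lost it (Fisher's exact test, two-sided, adjusted p = 1.7e-32 over 8 tests). In 35S::ULT1, 4 of 656 genes that gained H3K27me3 and carried K4 in Ler (0.610%) lost it. Of the other genes chosen in the same way, 0.0273% did (Fisher's exact test, adjusted p = 0.000815). Of 151 genes that lost H3K27me3 in ref6-3 and carried no K4 mark in either Col-0 library, 6 (3.97%) gained K4. Of the other genes marked by H3K27me3 and not by K4 in Col-0, 0.809% did (Fisher's exact test, adjusted p = 0.00576). This ended under the 20% setting of the cover minimum (adjusted p = 0.258) and with equal numbers of peaks (adjusted p = 0.0627). The relation did not pass in ult1-2 (both adjusted p = 1) or ult1-3 (adjusted p = 0.0829 and 0.0864). For K4 losses in ult1-3 the adjusted p was 0.0436 under the 20% setting (Fisher's exact test). Of the genes gained in 35S::ULT1, 55.9% carried K4 trimethylation in Ler, and of those gained in ref6-3 45.6% carried it in Col-0, against 76.0% and 77.1% of genes that could be gained.

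The 9 gene lists were then followed through the single-end genotypes. Of the floral identity genes 20 of 22 were marked in every library of each genotype, of the meristem and boundary genes 22 of 23, and of the seed and embryo genes 19 of 20, while 0 of 14 housekeeping genes were marked. Since ult1-2 lost only 2.64% of all marked genes, lists this short would mostly lose none in any case. Flowering time genes were marked in 15 of 29 cases in Ler, 13 in ult1-2, 14 in ult1-3 and 17 in 35S::ULT1. Auxin genes were marked in 15 of 21 cases in Ler and 17 in ref6-3, root genes in 9 of 12 in Ler, leaf polarity genes in 9 of 14 and Polycomb and Trithorax genes in 3 of 29. Among 144 list tests 1 passed: 3 of 13 leaf polarity genes lost K4 trimethylation in 35S::ULT1, against 0.120% of all genes that could (Fisher's exact test, two-sided, p = 4.23e-07, adjusted p = 6.1e-05). These were YAB5 (28.1% ± 7.95 to 0% ± 0), YAB1 (39.6% ± 11.2 to 7.91% ± 11.2) and YAB2 (19.6% ± 7.05 to 4.99% ± 7.05), YABBY factors of the lower leaf side. No list passed under the 20% setting of the cover minimum, and each of the 3 genes had a limma adjusted p of 1.

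Gene by gene with limma and the floor, list members passed in few cases. For H3K27me3 in 35S::ULT1, 2 of 21 flowering time genes tested passed over all genes and 2 adjusted over the list alone, for Polycomb and Trithorax genes 1 and 4 of 9, and for floral identity genes 1 and 0 of 21. The passing genes over all genes were SPL3, TEM2 (0% ± 0 to 49.4% ± 0, adjusted p = 0.0346), the demethylase gene JMJ30 (0% ± 0 to 52.4% ± 5.09, adjusted p = 0.0232) and SPT (0% ± 0 to 39.8% ± 0, adjusted p = 0.0486). In ref6-3, flowering time genes gave 1 over all genes and 1 adjusted over the list alone, auxin genes 2 and 2, and root genes 1 and 1, these being AGL18, YUC3 and PIN7, and WER, a MYB factor of root hair patterning. In ult1-2 only ULT1 passed adjusted over the list alone, for Polycomb and Trithorax genes. For K4 in 35S::ULT1, 1 meristem and boundary gene, BRC1, passed both ways, and SEP3, the dormancy gene DOG1 and YAB5 passed adjusted over the floral identity, seed and embryo and leaf polarity list alone, 1 gene each. In ref6-3, DOG1, the 1 seed and embryo gene tested, did. WER, DOG1 in ref6-3 and the members named for the list alone were picked out after their values were seen.

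The paired-end series asked what ult1-3 changed in Col-0 and on top of clf-28 or swn-7. In ult1-3, H3K27me3 was lost from ULT2, the paralog of ULT1 (85.5% to 0%), from YUC8, another auxin synthesis gene (98.2% to 0%), and from TPPI, a trehalose phosphatase gene (87.3% to 0%). In the double mutants with the same allele, ULT2 was at 61.8% in ult1-3 clf-28 and 47.4% in ult1-3 swn-7, and YUC8 was at 0% and 100%, values looked up after the losses in ult1-3 were seen. In clf-28 it was lost from FLC, the flowering repressor (95.9% to 16.5%), from KNAT2, a KNOX homeobox gene (98.8% to 20.6%), and from the embryo regulator LEC2 (100% to 29.1%), and gained at KNU, a zinc-finger gene of floral meristems, and JMJ32, a demethylase gene (both 0% to 100%). In swn-7, KNU was gained too (0% to 100%) and DAA1 was lost (88.3% to 0%). KNU was at 0% in ult1-3 and ult1-3 swn-7. Of 22 floral identity genes, 18 were marked in the paired-end Col-0 list and 20 in both single-end Col-0 libraries. The state of KNU in those libraries is not given here, so its gain rests on the paired-end Col-0 list. DAA1 was at 0% in ult1-3 and ult1-3 swn-7 as well, and at 0% ± 0 in the single-end Col-0 libraries. Its loss was therefore not particular to swn-7 and rests on the paired-end Col-0 list. In ult1-3 clf-28, FLC and MAF4 (84.8% in Col-0), SPL4 (100%), CNA (100%), a class III HD-ZIP gene, and TAA1 (100%), an aminotransferase of auxin synthesis, were at 0%. In ult1-3 swn-7, CNA and AGL15, a MADS-box gene (92.5%), were at 0%, and AGL15 was at 0% in ult1-3 clf-28 as well.

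**Figure D2:**
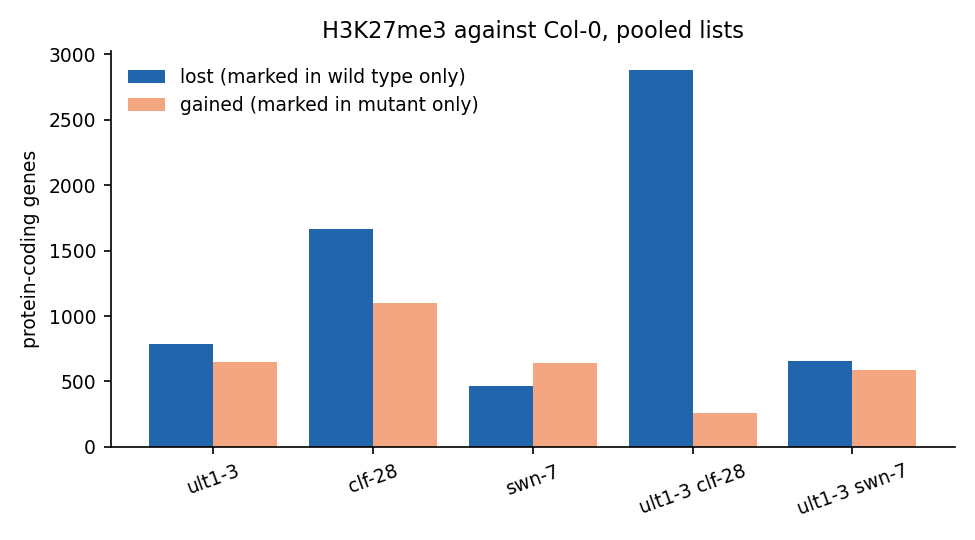
Protein-coding genes that lost or gained H3K27me3 against Col-0 in each mutant of the paired-end series, 1 list per genotype, with the vertical axis in genes. The ult1-3 clf-28 list lacked 2883 genes of Col-0 and clf-28 lacked 1662.

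Of the 5681 genes marked in Col-0, 783 (13.8%) were not marked in ult1-3, 1662 (29.3%) in clf-28, 464 (8.17%) in swn-7, 2883 (50.7%) in ult1-3 clf-28 and 653 (11.5%) in ult1-3 swn-7. Gains numbered 649, 1102, 644, 259 and 584 in the same order. Going from clf-28 to ult1-3 clf-28, 2308 genes were no longer marked and 244 were newly marked; from swn-7 to ult1-3 swn-7 these numbers were 543 and 294. Of the Col-0 genes, 1056 (18.6%) were marked in both ult1-3 and clf-28 and not in ult1-3 clf-28, and 2615 (46.0%) were marked in all 4. Of the 464 genes lost in swn-7, 255 were also unmarked in both ult1-3 and ult1-3 swn-7. All these comparisons share the 1 Col-0 list. The ult1-3 clf-28 list was also the shortest, with 3703 peaks over 9.55 Mb against 5357 over 18.9 Mb in Col-0. With 3703 peaks in every list, 2271 genes (46.9%) were lost and 489 gained in ult1-3 clf-28, 1797 (37.1%) were lost in clf-28, and 1333 genes of clf-28 were not marked in ult1-3 clf-28, with 462 in reverse. With 1 list per genotype no test was possible, and gains in ult1-3 clf-28 were 652 with a minimum of 1 covered bp and 670 over all annotated genes. Gains in clf-28 were 1686 with a minimum of 1 bp and 674 with a minimum of 80% cover, and losses in swn-7 were 705 with a minimum of 1 bp.

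**Figure D3:**
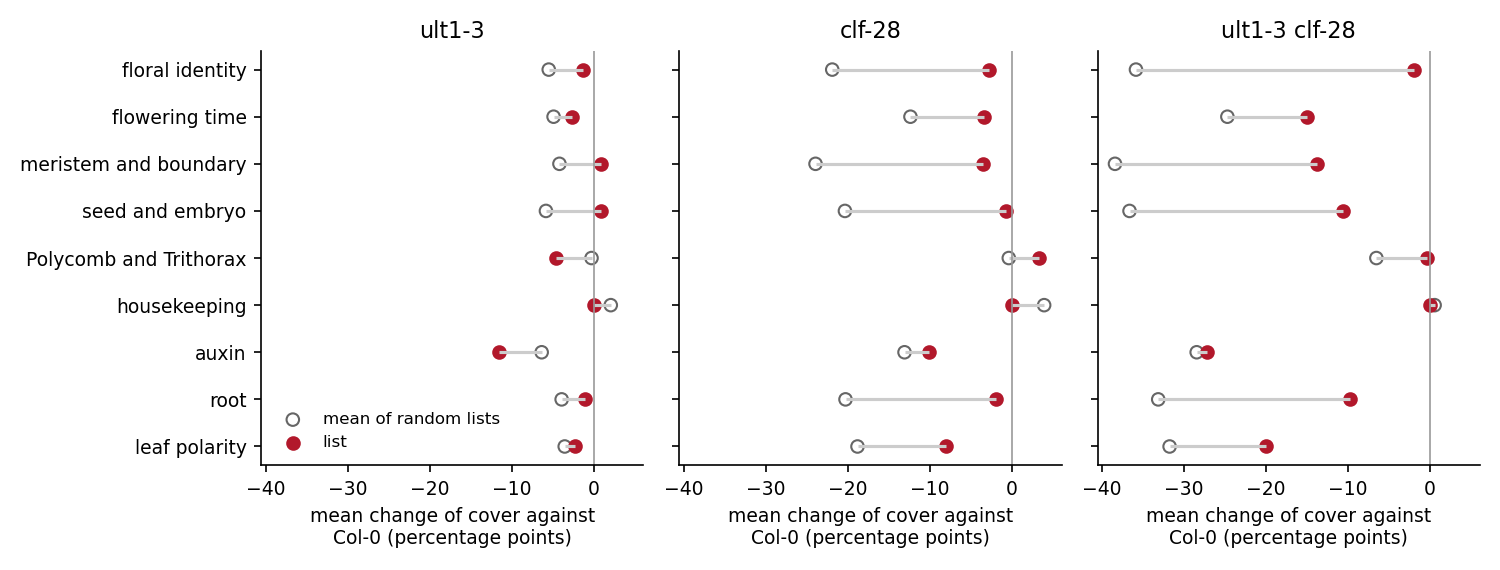
Mean change of H3K27me3 cover against Col-0, in percentage points, for the 9 gene lists (filled points) in ult1-3, clf-28 and ult1-3 clf-28, beside the mean of 10000 random lists matched on cover and peak width in Col-0 (open points). Floral identity genes changed by -1.94 points in ult1-3 clf-28, against -35.9 for random lists.

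In ult1-3 clf-28, some developmental regulators kept H3K27me3 and others lost it. AG, SEP2, SEP3 and AP1, floral MADS-box genes, and STM, WUS and CLV3, meristem regulators, were covered for 100% in this list; these list members fall outside the rule for named genes and were chosen after their values were seen. Of 18 floral identity genes marked in Col-0 1 was lost (SHP1, 88.1% to 36.7%), of 19 meristem and boundary genes 3, of 16 seed and embryo genes 3, of 8 root genes 0 and of 5 Polycomb and Trithorax genes 0. Of 16 flowering time genes 6 were lost, of 12 auxin genes 6 and of 10 leaf polarity genes 3. The median change of the floral identity, meristem and boundary, and seed and embryo lists was 0 points, at percentiles 76.3, 81.0 and 92.7 of random lists; flowering time, auxin, root, leaf polarity, Polycomb and Trithorax and housekeeping lists stood at percentiles 4.64, 30.1, 64.8, 53.0, 0 and 0. Medians of 0 tie with many random lists, so mean changes were added after the data were seen. The mean change was -1.94 points for floral identity genes (percentile 100), -13.8 for meristem and boundary genes (percentile 99.8), -10.6 for seed and embryo genes (percentile 99.9) and -27.3 for auxin genes (percentile 58.2). With random lists matched also on the width of the Col-0 peak, 0 of 10000 random lists had a mean change as high as the floral identity list. KNU, which went from 0% to 100% in ult1-3 clf-28, carried part of this: without it, singled out after its values were seen, the mean change of the other 21 genes was -6.80 points (percentile 99.99). In the other lists the mean change was -15.0 (flowering time, percentile 95.8), -9.71 (root, 98.7), -20.0 (leaf polarity, 88.5), -0.420 (Polycomb and Trithorax, 96.7) and 0 (housekeeping, 57.0). The clf-28 list alone also stood high for floral identity genes (mean change -2.84, percentile 99.6), meristem and boundary genes (-3.48, 99.6) and seed and embryo genes (-0.757, 99.6).

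The wild types differed more than the mutants of ULT1 did. Col-0 lost 653 genes and gained 391 in H3K27me3 against Ler, with 33 and 28 calls in the other 2 splits, and lost 235 and gained 362 in K4. Ler sequence missing from the reference build can look like a missing peak in Ler, which would count as a gain in Col-0. Not all gains need therefore be differences in the marks, here and wherever the Col-0 state is used. No difference in the density of calls was detected within 3 Mb of ULT1 on chromosome 4: in ult1-3, 19 of 1714 genes there (1.11%) and 0.777% elsewhere had an H3K27me3 call (Fisher's exact test, two-sided, p = 0.158, adjusted p = 0.313 over 6 tests), and p was 0.163 in ult1-2, 0.166 in 35S::ULT1 and, for K4, 0.209, 0.806 and 0.518 in ult1-3, ult1-2 and 35S::ULT1. Within 5 Mb, ult1-2 had fewer H3K27me3 calls near ULT1 (0.484% against 1.03%; Fisher's exact test, two-sided, p = 0.00377, adjusted p = 0.0226 over 6 tests). Within 1 Mb, 5 of 585 genes had a K4 call in 35S::ULT1 (0.855% against 0.324%), which did not pass after adjustment (Fisher's exact test, two-sided, p = 0.0470, adjusted p = 0.282). The single-end and paired-end Col-0 data shared 5018 marked genes, 88.3% of the 5681 in the paired-end list. This was 79.6% of the 6304 genes marked in both single-end libraries and 72.0% of the genes marked in either series. For K4, 790 genes were gained in Col-0 without Ler library 3 and 450 were lost without Ler library 1, and 666 genes were gained in H3K27me3 over all annotated genes.

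**Figure D4:**
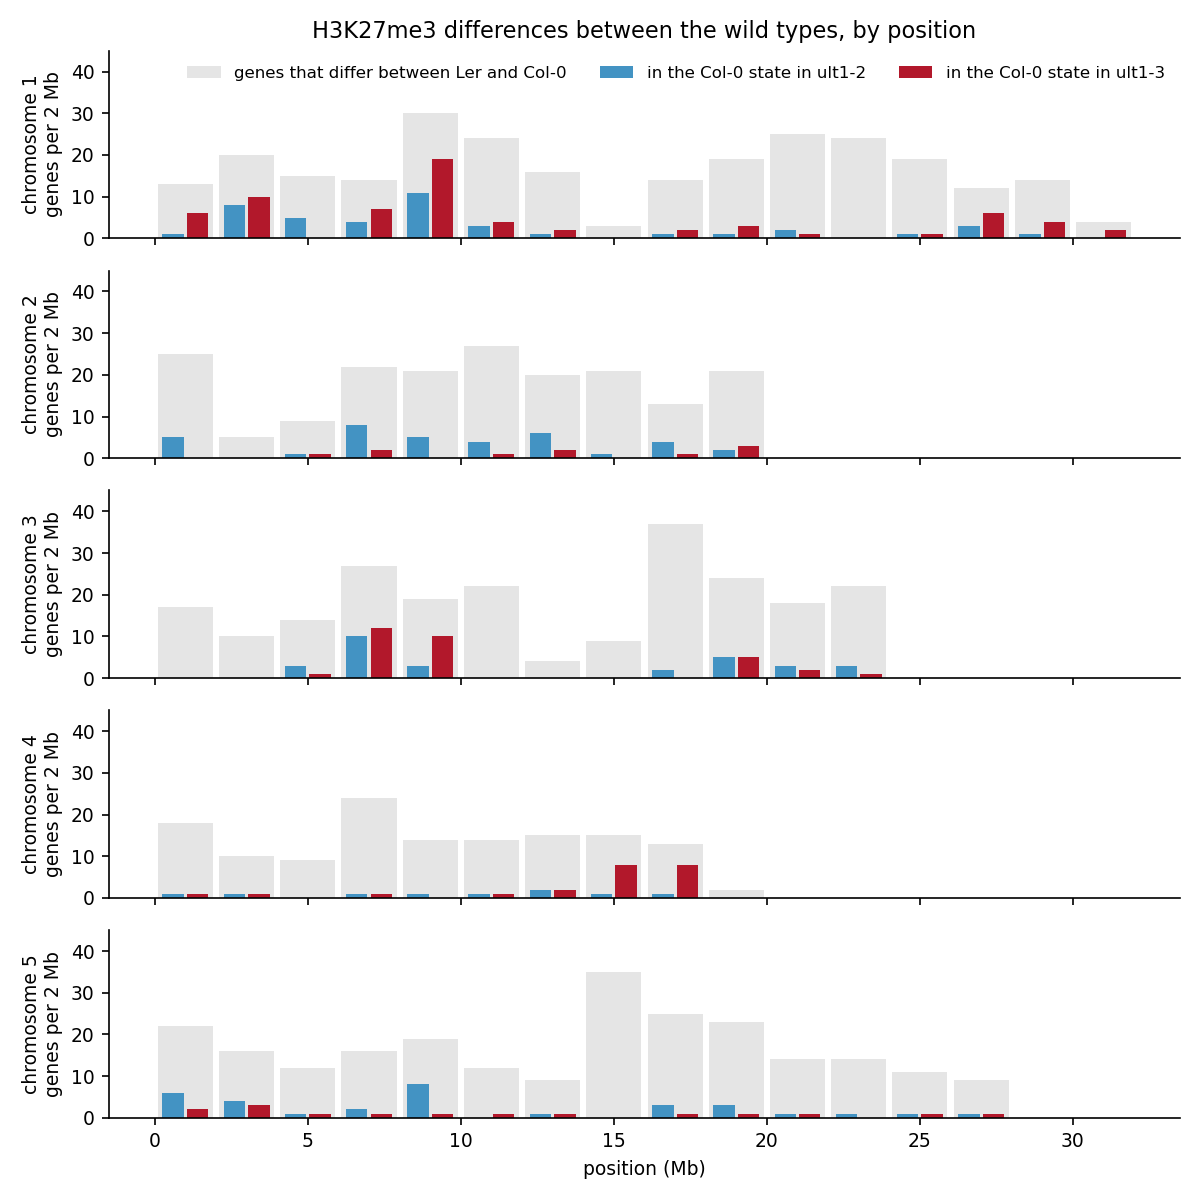
Genes whose H3K27me3 state differed between Ler and Col-0, in windows of 2 Mb along the 5 chromosomes (grey), and those among them that were in the Col-0 state in both ult1-2 libraries (blue) or both ult1-3 libraries (red), with position in Mb on the horizontal axis and genes per window on the vertical axis. In chromosome 4 from 14 to 16 Mb, 8 of 15 such genes were in the Col-0 state in ult1-3 and 1 in ult1-2. In chromosome 1 from 8 to 10 Mb, 19 of 30 were in ult1-3 and 11 in ult1-2.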

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

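The H3K27me3 list of Col-0 library 1 held 3 peaks on the chloroplast genome, which no comparison of the report used and no other single-end or paired-end list held. Chloroplast DNA carries no histones. They spanned positions 1 to 101000, 107601 to 131000 and 137601 to 154400, with 93038, 21251 and 18402 ChIP reads against 201204, 46311 and 33553 control reads. Raw ChIP counts were below the raw control counts in all 3 peaks, and the difference between this library and the others was not tested.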

How the results depend on the processing

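Of the values recomputed under alternatives, 437 kept their call or stayed within 1.5 times (496 with the merging of peaks), 164 moved, 5 newly passed a threshold, 3 no longer passed and 0 reversed. Of 338 named genes with a call 114 kept it under every alternative and 0 took the opposite call. The variance floor, the mean in place of the median, matching on peak width and equal peak numbers in the paired-end lists were chosen after the data were seen. Read depth before peak calling was not used here, so a gene without a peak is not shown to lack the mark. Merging peaks within 600 bp had nothing to change, since no 2 peaks were closer. Without a filter, limma could not be fitted for H3K27me3 in either family or for K4 in Col-0 and ref6-3, and on only the 2 groups compared it could not be fitted for H3K27me3 in ult1-2 and ult1-3. Except where the construction shows it, the cause was not tested.

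With all annotated genes, H3K27me3 gains were 149 (ult1-2), 123 (ult1-3) and 666 (Col-0 against Ler), losses in 35S::ULT1 139, and K4 gains in ult1-2 55. In ult1-3 clf-28, gains were 670, and 592 and 717 genes were new against clf-28 and ult1-3. With 1 covered bp, losses of H3K27me3 in ult1-3 were 225 and of K4 49, gains in clf-28 1686, losses in swn-7 705 and gains in ult1-3 clf-28 652. New genes against clf-28, ult1-3 and swn-7 were 489, 693 and 503. Under the 20% setting, K4 losses in ult1-3 were 49 and list tests past the threshold 0. The relations of marks had adjusted p of 0.0436 (ult1-3) and 0.258 (ref6-3) by Fisher's exact test. Shared H3K27me3 losses of ult1-2 and ult1-3 were 115. K4 gains that 35S::ULT1 shared were 5 (ult1-2) and 4 (ult1-3), and K4 losses 5 (ult1-3). Under the 80% setting, K4 gains were 101 (ult1-2), 137 (35S::ULT1) and 336 (ref6-3), and K4 losses 155 (ult1-3), 31 (35S::ULT1) and 412 (Col-0). Gains in clf-28 were 674 there, and 1485 genes of clf-28 were absent from ult1-3 clf-28. With the stricter threshold, K4 losses were 18, 47 and 13 in ult1-2, ult1-3 and 35S::ULT1.

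With equal numbers of peaks, H3K27me3 losses and gains in 35S::ULT1 were 137 and 655 and limma calls 1448. K4 losses were 24 (ult1-2) and 35 (35S::ULT1) and K4 gains 56 (ult1-2). Gains in ult1-3 clf-28 were 489, 1333 genes of clf-28 were absent from it, and 462 and 530 were new against clf-28 and ult1-3. The ref6-3 relation had adjusted p of 0.0627. Losses that 35S::ULT1 shared were 9 (ult1-2) and 7 (ult1-3), and K4 gains shared with ult1-2 17. With the variance floor, limma calls for H3K27me3 were 711 (35S::ULT1), 0 (ult1-2) and 0 (ult1-3), and for K4 3, 0, 2 and, in ref6-3, 147. On only the 2 groups compared, K4 calls were 393 (35S::ULT1), 366 (ult1-2) and 430 (ult1-3). The mean in place of the median put 6 lists above the 95th percentile in ult1-3 clf-28, 3 in clf-28, 3 in swn-7, 2 in ult1-3 and 2 in ult1-3 swn-7, against 0 each, and matching also on width 6, 5, 3, 0 and 2 in the same order. Position tests gave p = 0.0470 for K4 in 35S::ULT1 (1 Mb) and p = 0.00377 for H3K27me3 in ult1-2 (5 Mb; both Fisher's exact).

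With the library number as a replicate block, exact permutation p was 0.0833 for H3K27me3 peaks and 0.0417 for K4 peaks and for K4 peak similarity, against 0.0476, 0.781 and 0.781 without it, so the call changed in all 3. Block fits of limma called 288, 316, 2362 and 1457 genes for H3K27me3 in ult1-2, ult1-3, 35S::ULT1 and ref6-3, and 131, 179, 139 and 1513 for K4. Deviations of same-numbered libraries correlated by 0.451 to 0.546 for K4 in the Ler family and -0.0287 to 0.451 for H3K27me3. The labels give only a number, so nothing was crossed.

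Leaving out 1 library loosens the rule, so its counts could not fall; the lone library was assumed to vary like the others in limma. Ranges for H3K27me3 losses and gains were 225 to 456 and 98 to 169 (ult1-2), 158 to 484 and 83 to 205 (ult1-3), and losses 75 to 101 (35S::ULT1) and 236 to 379 (ref6-3). For K4 they were 88 to 249 and 58 to 220 (ult1-2), 90 to 431 and 69 to 232 (ult1-3), 35 to 192 and 135 to 337 (35S::ULT1), 72 to 165 and 150 to 303 (ref6-3), and 321 to 450 and 394 to 790 (Col-0). Limma calls were 448 to 565, 486 to 700, 855 to 2536 and 840 to 2628 for H3K27me3 in ult1-2, ult1-3, 35S::ULT1 and ref6-3, and 287 to 609, 321 to 1019, 286 to 635 and 2446 to 3238 for K4.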

Other observations

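The tests of reads in peaks, stricter threshold, equal peak numbers and position near ULT1 were chosen after the result was seen, and those of uncovered genes and of the shared losses before theirs.

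Losses recurred across the 2 series, which share no libraries. Of 4992 genes marked in both wild types, 36 were lost in ult1-2 against Ler and 535 in ult1-3 against Col-0 in the paired-end series, and 21 in both, against 3.86 for independent lists (Fisher's exact test, two-sided, p = 3.52e-12, adjusted p = 1.93e-11 over 11 overlaps). For single-end ult1-3, 11 of 24 were shared against 2.57 (Fisher's exact p = 1.31e-05, adjusted p = 3.61e-05). The clf-28 and swn-7 lists, which have intact ULT1, shared losses too: clf-28 shared 19 with ult1-2 against 8.95 (Fisher's exact p = 0.000317, adjusted p = 0.000580) and 9 with ult1-3 against 5.97 (adjusted p = 0.158), and swn-7 shared 6 with each, against 1.17 (Fisher's exact p = 0.000924, adjusted p = 0.00145) and 0.779 (p = 8.82e-05, adjusted p = 0.000194). Genes under Col-0 peaks of at most 2 kb were lost in 30.2% of cases in paired-end ult1-3, and those under peaks over 8 kb in 4.36%; in ult1-3 clf-28 these were 60.7% and 48.0%.

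The first pattern was the gain of H3K27me3 in 35S::ULT1. More reads in peaks did not account for it, since 3 of 6 libraries of Ler, ult1-2 and ult1-3 held as many reads and marked 7060 to 7192 genes. The longer peak lists did not account for all of it, since with equal numbers of peaks 655 genes were still gained and 137 lost; this setting removes more peaks from 35S::ULT1 than from the other genotypes by construction, so the drop from 1173 does not show what list length contributed. Extra peaks near the calling threshold stay open: 1168 genes were gained under the stricter q, but this removed only 4.03% and 4.16% of the peaks. The new peaks held 415 and 382 reads per kb against 692 and 629 in the others. Most of them still passed the stricter q, 82.5% and 83.7% of the new peaks against 99.4% and 99.3% of the others. Among 17912 genes with no covered bp in the wild types, 156 were gained in both 35S::ULT1 and ref6-3 against 29.8 for independent lists (Fisher's exact test, two-sided, p = 2.58e-70). Some genes may be open to gains of H3K27me3 whichever regulator is altered, and an effect of ULT1 level itself was not separated from other differences between these 2 libraries and Ler.

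The second pattern was the Col-0 state of ult1-3 near ULT1. Of the 43 genes within 3 Mb that differed between Ler and Col-0 in H3K27me3, 16 (37.2%) were in the Col-0 state in ult1-3 against 12.9% elsewhere (Fisher's exact test, two-sided, p = 7.98e-05, adjusted p = 0.000479 over 6 tests). In ult1-2 the shares were 9.30% and 14.4% (Fisher's exact p = 0.502), so loss of ULT1 function did not account for it in H3K27me3. For K4 in ult1-3 they were 32.1% and 13.7% (Fisher's exact p = 0.0127, adjusted p = 0.0381). For K4 in ult1-2 they were 14.3% and 6.85% (Fisher's exact p = 0.134, adjusted p = 0.269), which leaves loss of ULT1 function open for K4. Col-0 sequence linked to the ult1-3 allele could give this, though neighbouring genes share peaks, which makes p too small, and no sequence was examined. The Col-0 state was not particular to this region. In ult1-3 it held 19 of 30 such genes on chromosome 1 from 8 to 10 Mb. It held 10 of 19 on chromosome 3 from 8 to 10 Mb, and 0 of 24 on chromosome 1 from 22 to 24 Mb. These windows, picked after their values were seen, are not on the chromosome of ULT1, so linkage to the allele cannot account for them.

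The third pattern was the 76 genes that lost H3K27me3 in both ult1-2 and ult1-3. Ler libraries that stand apart from all others did not account for them: 2 (2.63%) were unmarked in both 35S::ULT1 libraries and 70 were marked in both, against 11.1 for genes of the same cover in the mutants that Ler left unmarked too. This comparison with other genes was added after the result was seen. In Col-0, 54 of the 76 were lost too, a count that uses the same Ler libraries. Of all genes marked in Ler 9.38% were lost in Col-0, and of simulated losses 37.1%. In some windows both mutants were in the Col-0 state at many genes that differed between the wild types. On chromosome 1 from 8 to 10 Mb these were 11 (ult1-2) and 19 (ult1-3) of 30. On chromosome 3 they were 10 and 12 of 27 from 6 to 8 Mb, and 2 and 0 of 37 from 16 to 18 Mb. Col-0 sequence in both mutant lines could give this and was not tested. The median cover of the 76 genes in Ler was 66.0% against 100% for all marked genes, so many were only just marked in Ler and small changes of peak edges could remove them.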
